A study of Mus musculus with 2 samples.

How the data were processed

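Total RNA (1 ug) from bone marrow and from heart Nestin+ cells was made into 1 standard Illumina library each, per the labels' protocols. The values used here are RPKM, read counts divided by the length of the gene model and by the size of the library, as deposited by the authors, per the file headers, with a gene name, chromosome and region for each of 49585 rows. No log transform and no scaling between the libraries is recorded. The aligner, the counting tool and the use of strand are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The genome build is mm8, per the submitters' processing notes, but 45149 rows (91.1%) have the chromosome, start, end and strand of a GENCODE M21 gene model on GRCm38, and coordinates are given as in the files and read on GRCm38.

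Read depth was recovered from the RPKM values. With the exon-union lengths of the matching gene models, the values are whole multiples of what 1 read is worth, which gave totals of 53999963 reads for bone marrow and 64872683 for heart, a ratio of 1.20. Of 13877 genes with a known length and above 0 in both libraries, 11963 (86.2%) came out whole in both within a tolerance of 0.02 reads, where chance gives 0.16%. For these genes an exact conditional (Clopper-Pearson) 95% interval of the ratio was computed. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. The reads are derived values, and no count model was fitted. For a gene with 0 reads in a library the fold is given against a floor of 3 reads, beside the lower limit of the interval.

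The 26 rows with a date-like name were renamed by their region. Rows sharing a symbol, including 186 with numbered repeat names, were represented by the row with the highest mean, leaving 49492 symbols. All 5751 rows for mitochondrial ribosomal and transfer RNA and for small RNA classes were at 0 in both libraries, mt-Rnr1 included, so an exact 0 is reported as listed at 0 unless reads are given.

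The main value of a gene was log2((heart + 1)/(bone marrow + 1)) on RPKM, and each log2 ratio printed is on that scale, which understates differences of low genes. A gene counted as higher in a library when this was at least 1 in size and the higher library was at or above 5 RPKM. With 1 library per tissue there is no replicate spread, and no p-value or standard error was computed. For each of 34 gene lists (633 of 634 symbols found), the median over members at or above 1 RPKM in either library was placed among 10000 random lists of the same size matched on 20 bins of mean expression. A list was described with at least 5 such members and stood apart outside the central 95% of the random lists. Members called neither are those at or above 1 RPKM that did not meet the 2-fold rule.

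Named genes followed a rule fixed before the data were examined. It takes Postn and Nes, the 12 genes with the largest ratio in each direction among those at or above 20 RPKM with at least 50 reads in the higher library, up to 4 members of each list with the largest ratio at or above 5 RPKM, the 5 most abundant genes of each library, and all sex-linked genes of the list. Predicted genes and pseudogenes were not named. Some genes that the rule takes are not reported here. Col1a1, Col1a2, Nkx2-5, Ptprc, Cdh5, Dmp1, Hoxa5, Flt1, Vwf, Cd53, Cd14, Lyz2 and, in the scatter plot, Col3a1 and Thbs1 are outside the rule and were chosen after their values were seen. The same holds for Rgs5, Kcnj8, Abcc9, Myh11, Des, Pparg, Csf1, Il34, Tgfb2, Tgfb3, Ptgs2, Hmox1, Tbx18, Wt1, Tcf21, Hand2 and Gata4.

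Alternatives fixed in advance were pseudocounts of 0.1 and 5, floors of 1, 20 and none, a 4-fold threshold, summed rows, other list filters, and scaling by the median ratio, the upper quartile, a trimmed mean of log ratios (30% of ratios and 5% of levels trimmed from each end, unweighted) or the RPKM sum without mitochondrial and the 20 most abundant genes. Scaling to the same RPKM sum and leaving out chromosome 10 were chosen after seeing the data. RPKM sums stood in for read totals in the alternatives because lengths were not known for all genes.

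The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data of 49585 rows drawn at both depths. Both totals were recovered exactly, all genes changed 3-, 4-, 8- or 16-fold were counted in the right direction, and 0 of 6866 unchanged genes were counted. The intervals covered the simulated fold for 97.5% of genes, and 1 of 40 lists of unchanged genes was called apart. The changed genes were drawn from genes with a mean above the floor of 5 RPKM, so folds and intervals of lower genes were not tested. The simulation holds counting noise only.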

Results

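RNA sequencing compared cultured Nestin+ mesenchymal stromal cells from the bone marrow and from the heart of mice 7 days old. Nestin is an intermediate filament protein, and the mice carry a green fluorescent reporter driven by its gene. Both cultures were at passage 10, and each tissue gave 1 library, so no difference below has a replicate check. The heart cells were grown with EGF and bFGF at 20 ng/ml each and cardiotrophin-1 at 4 ng/ml, and the bone marrow cells in another medium, so tissue and medium cannot be separated. The reads recovered from the deposited values came to 53999963 for bone marrow and 64872683 for heart. Of 49585 gene rows, 10609 in bone marrow and 10643 in heart reached 1 RPKM (reads scaled by the length of the gene model and the size of the library).

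Proliferation genes and the contractile genes of the smooth muscle and pericyte list were mostly higher in bone marrow. Spp1, which encodes the secreted phosphoprotein osteopontin, stood at 7438 RPKM in heart and 113 in bone marrow. Acta2, which encodes smooth muscle alpha-actin, stood at 889 RPKM in bone marrow and 40.1 in heart. The collagen genes Col1a1 and Col1a2 differed little, with log2 ratios of heart over bone marrow of -0.02 and 0.03. Postn, which encodes the matricellular protein periostin, was abundant in both libraries. Its log2 ratio of -0.17 was close to the median of -0.14 over genes at or above 5 RPKM in both.

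Among 7659 genes at or above 5 RPKM in the higher library, 579 (7.56%) were at least 2-fold higher in heart and 728 (9.51%) were at least 2-fold higher in bone marrow. The other 6352 (82.9%) lay within 2-fold. Heart genes made up 44.3% of those 2-fold apart. The median log2 ratio of the 6049 genes at or above 5 RPKM in both libraries was -0.14. Setting that median to 0 adds 0.15 to the log2 ratio of abundant genes and gives 704 genes higher in heart and 583 higher in bone marrow, a heart share of 54.7%. Which library had more 2-fold genes therefore depends on the scaling. At least 8-fold differences numbered 122 toward heart and 89 toward bone marrow. Across the 21620 genes above 0 in either library, Pearson's r was 0.936 and Spearman's rho 0.894; genes are not independent replicates.

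**Figure D1:**
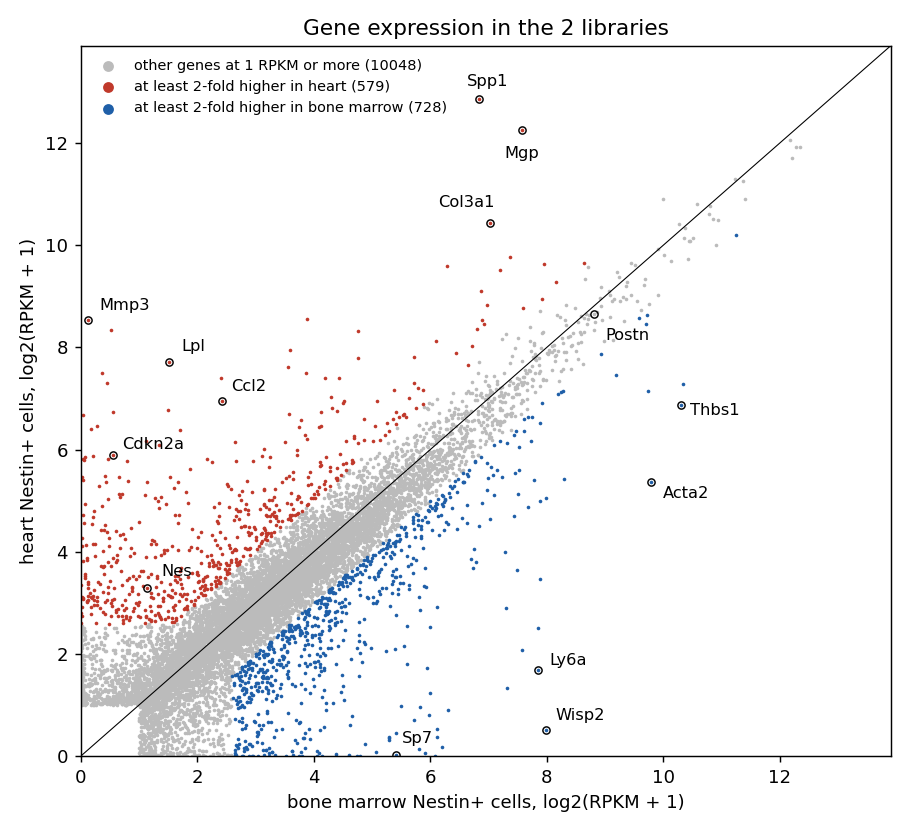
Each point is a gene at or above 1 RPKM in either library, with its log2(RPKM + 1) in bone marrow on the horizontal axis and in heart on the vertical axis; the diagonal marks equal values. Red points are the 579 genes at least 2-fold higher in heart and blue points the 728 at least 2-fold higher in bone marrow, with Spp1 and Mgp at the top and Postn close to the diagonal.

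The series title concerns periostin of heart Nestin+ cells and the state of macrophages, so Postn and Nes were read first. Postn (chromosome 3, 54361109 to 54391037, plus strand, GRCm38 gene model) stood at 448 RPKM in bone marrow and 399 in heart, from 210625 and 225520 reads. The ratio of heart to bone marrow was 0.891 with a 95% counting interval of 0.886 to 0.897, and its log2 ratio was -0.17, close to the all-gene median. Nes (chromosome 3, 87971078 to 87980451, plus strand) stood at 1.20 RPKM in bone marrow and 8.74 in heart, from 416 and 3639 reads. It was 7.28-fold higher in heart, with a counting interval of 6.58 to 8.08. The interval covers counting error in these 2 libraries only.

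The genes with the largest ratios toward heart encode secreted and surface proteins. Mmp3, the matrix protease stromelysin, stood at 369 RPKM in heart and 0.0925 in bone marrow, a log2 ratio of 8.40. Serpina3n, an acute phase inhibitor of serine proteases, reached 322 RPKM in heart and 0.440 in bone marrow, and the acute phase protein gene Saa3 reached 179 and 0.284. The chemokine genes Ccl8 and Ccl11 had log2 ratios of 6.86 and 6.62. Calcrl, which encodes a receptor for adrenomedullin and the calcitonin gene-related peptide, had 6.22, and Lpl, which encodes lipoprotein lipase, had 6.20. Cp, which encodes the copper-carrying ceruloplasmin, stood at 105 RPKM in heart and 0.474 in bone marrow. The remaining 4 of the 12 were Pi15, Spp1, Olr1, which encodes a receptor for oxidized low density lipoprotein, and Ace, which encodes the angiotensin-converting enzyme, with log2 ratios of 6.16, 6.03, 5.79 and 5.79. Serpina3n, Saa3 and the chemokine genes have close relatives, and reads shared between such copies make their values uncertain.

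The genes with the largest ratios toward bone marrow included matrix, bone and contractile genes. Wisp2, a member of the CCN family of matricellular proteins, stood at 253 RPKM in bone marrow and 0.433 in heart, a log2 ratio of -7.47. Ly6a, which encodes the stem cell antigen Sca-1, stood at 229 and 2.23 RPKM. Rpl39l, a close relative of a ribosomal protein gene, had 3002 reads in bone marrow and 0 in heart. The lower 95% counting limit of its fold was 977, and the fold against a floor of 3 reads was 1202. Reads shared with its relatives make it uncertain. Bmp4, a bone morphogenetic protein gene, stood at 73.0 RPKM in bone marrow and 0.132 in heart. Actg2, which encodes enteric smooth muscle gamma-actin, had a log2 ratio of -5.97. The small leucine-rich proteoglycan genes Omd, Fmod and Ogn had -5.83, -5.75 and -5.41. Ackr4, which encodes a chemokine-scavenging receptor, had -5.67, the collagen gene Col8a2 -5.58, the annexin gene Anxa8 -5.51 and Sp7, which encodes the osteoblast transcription factor osterix, -5.40.

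Of 34 gene lists fixed before the data were examined, 29 had at least 5 members at or above 1 RPKM. The median log2 ratio of 6 lists lay above the central 95% of 10000 random lists matched on expression, and that of 10 lists below it. Chance alone puts 5% of lists outside, and members of a pathway vary together, so random lists understate the spread. The percentiles describe these 2 libraries, not the tissues.

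**Figure D2:**
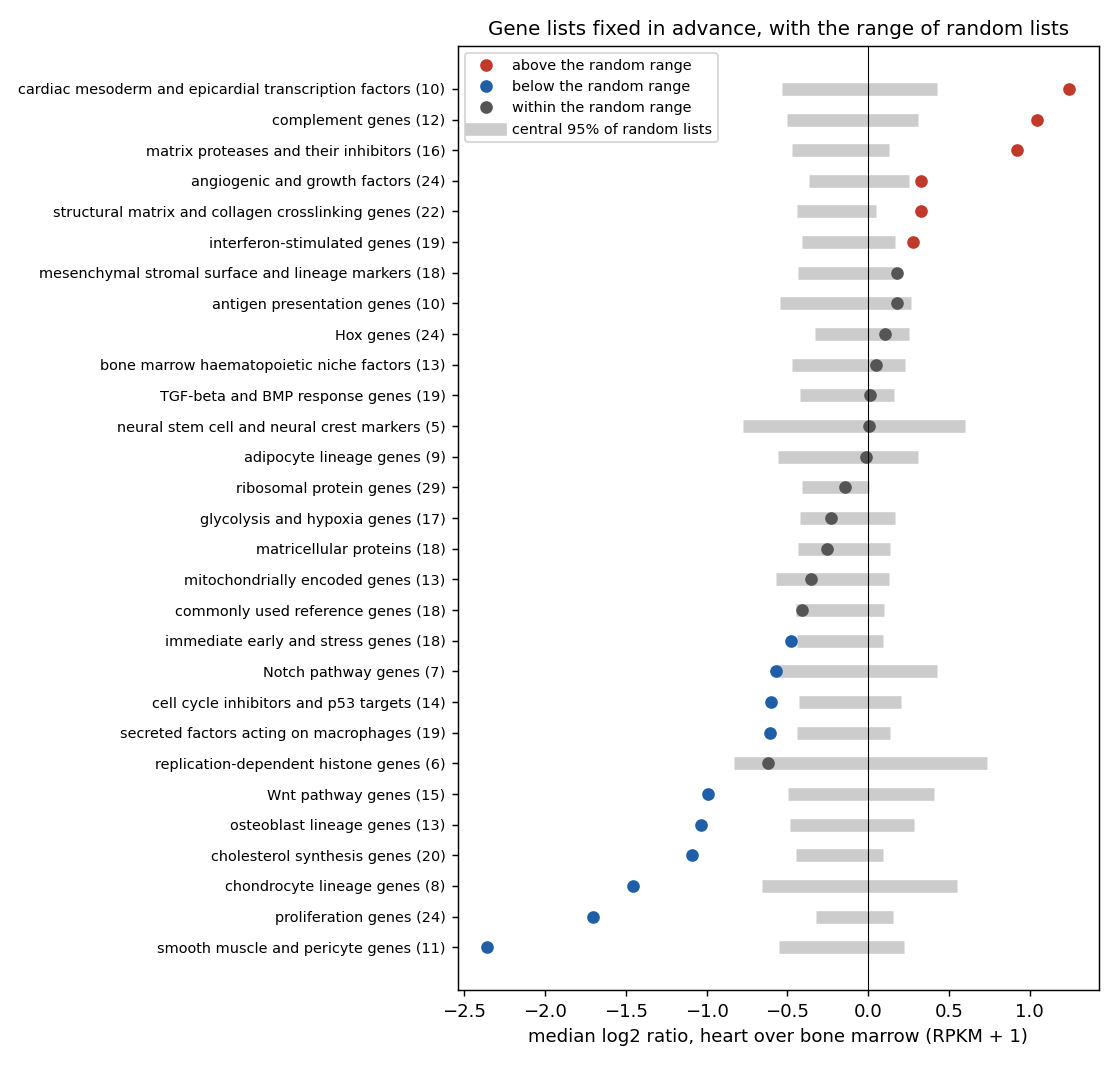
Points give the median log2 ratio of heart over bone marrow for each of the 29 lists, with the number of members at or above 1 RPKM in brackets, and grey bars the central 95% of medians of random lists matched on expression. Medians run from -2.36 for smooth muscle and pericyte genes to 1.25 for cardiac mesoderm and epicardial transcription factors.

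Smooth muscle and pericyte genes had the lowest median, -2.36. Of 11 members at or above 1 RPKM, 9 were at least 2-fold higher in bone marrow, 1 was higher in heart and 1 was neither. Acta2 had a log2 ratio of -4.44, the myosin light chain gene Myl9 -3.85 and the leiomodin gene Lmod1 -2.84. The gene higher in heart was Notch3, which encodes a receptor of mural cells, at 9.56 RPKM in heart and 3.05 in bone marrow. The pericyte genes Rgs5, Kcnj8 and Abcc9 were below 1 RPKM in both libraries, as were the muscle genes Myh11 and Des. The low median therefore describes mainly the contractile genes at or above 1 RPKM.

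Cell division genes were lower in heart almost throughout. Of 24 proliferation genes, 22 were at least 2-fold higher in bone marrow, none was higher in heart and 2 were neither, with a median of -1.70. Rrm2, which encodes a subunit of ribonucleotide reductase, stood at 60.9 RPKM in bone marrow and 2.33 in heart. The replication helicase genes Mcm3, Mcm6 and Mcm5 had log2 ratios of -2.25, -2.21 and -2.13. Cell cycle inhibitors and p53 targets also had a median toward bone marrow, -0.60, with 4 of 14 members higher there, 2 higher in heart and 8 neither. Those 2 were Cdkn2a, which encodes the inhibitor p16 and the p53 regulator p19ARF, at 58.9 RPKM in heart and 0.474 in bone marrow, and the neighbouring inhibitor gene Cdkn2b, at 10.6 and 0.0532. The p53 targets Mdm2 and Gdf15 were higher in bone marrow, with log2 ratios of -1.48 and -3.07.

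Skeletal lineage lists had medians toward bone marrow, with members both ways. Of 13 osteoblast genes at or above 1 RPKM, 7 were higher in bone marrow, 1 in heart and 5 neither, with a median of -1.03. Sp7 stood at 41.6 RPKM in bone marrow and 0.0106 in heart, and Alpl, which encodes tissue-nonspecific alkaline phosphatase, at 26.8 and 0.00764. Spp1 was the gene higher in heart. Dmp1, which encodes a dentin matrix protein and was chosen after its values were seen, also went toward heart, at 4.50 RPKM against 0.0536, under the floor of 5. Of 8 chondrocyte genes, 3 were higher in bone marrow, 1 in heart and 4 neither, with a median of -1.46; this list was no longer apart with all measured members kept. The cartilage collagen genes Col2a1 and Col11a1 had log2 ratios of -3.20 and -1.99 and the lubricin gene Prg4 -2.53, while Col10a1, a collagen gene of hypertrophic cartilage, stood at 108 RPKM in heart and 1.82 in bone marrow. Of 9 adipocyte genes, 4 were higher in heart and 5 neither, and the median of -0.02 lay within the random range, but above it with members below 5 RPKM left out. Those 4 were Lpl, the apolipoprotein gene Apoe (log2 ratio 4.22) and the transcription factor genes Cebpd and Cebpb (1.78 and 1.37). The transcription factor gene Pparg went toward bone marrow, at 4.85 RPKM against 0.658 in heart, under the floor of 5.

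Structural matrix genes and matrix proteases had medians toward heart, with large differences both ways. Of 22 structural matrix and crosslinking genes, 7 were higher in heart, 3 in bone marrow and 12 neither, with a median of 0.32. The proteoglycan genes Lum and Dcn had log2 ratios of 4.56 and 4.36, while the fibril-associated collagen gene Col12a1 stood at 230.0 RPKM in bone marrow and 4.67 in heart. Of 16 matrix proteases and inhibitors, 7 were higher in heart, 3 in bone marrow and 6 neither, with a median of 0.92. Mmp11, another matrix protease gene, had a log2 ratio of 2.40 and the collagenase gene Mmp13 -2.61. Matricellular proteins had a median of -0.25, within the random range, with 6 of 18 higher in heart, 7 in bone marrow and 5 neither. Tgfbi, which encodes a TGF-beta-induced adhesion protein, had 5.05 and Smoc2, which encodes a calcium-binding matrix protein, had -4.05.

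Secreted factors acting on macrophages did not move one way. Of 19 members at or above 1 RPKM, 5 were higher in heart, 9 in bone marrow and 5 neither, with a median of -0.61, below the random range. The 5 in heart were all chemokine or cytokine genes: Ccl2, Ccl7, Ccl8, Cxcl1 and Il6, with Ccl2 at 123 RPKM in heart and 4.38 in bone marrow and Il6 at 16.8 and 1.45. Ccl7 (log2 ratio 2.43) and Cxcl1 (2.54) were named after their values were seen. Gas6, which encodes a ligand of receptors used in clearing dying cells, stood at 109 RPKM in bone marrow and 12.9 in heart. The 9 in bone marrow also included the cytokine genes Csf1, Il34, Tgfb2 and Tgfb3, with log2 ratios of -1.25, -1.56, -2.15 and -1.54. Ptgs2 and Hmox1 (-2.22 and -2.36), also among the 9, encode enzymes, so the list does not hold secreted factors alone. With the 13 members below 1 RPKM kept, the median was 0.031 and the list lay above the random range, so its direction depends on that filter.

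Complement genes leaned toward heart, with 5 of 12 higher there, 3 in bone marrow and 4 neither, and a median of 1.05. The central component gene C3 stood at 20.6 RPKM in heart and 0.270 in bone marrow, while C2 was higher in bone marrow (-2.70). Of 24 angiogenic and growth factors, 4 were higher in heart, 3 in bone marrow and 17 neither, with a median of 0.33. Hgf, which encodes hepatocyte growth factor, and the lymphangiogenic factor gene Vegfc had log2 ratios of 3.96 and 3.49, and the placental growth factor gene Pgf had -2.94. Interferon-stimulated genes had a median of 0.28, above the random range, but only 1 of 19 was higher in heart, 1 in bone marrow and 17 neither. Interferon-stimulated genes and growth factors were no longer apart with members below 5 RPKM left out. Those 2 interferon-stimulated genes were Ifit3 (1.18) and Irgm1 (-1.67). Antigen presentation genes had a median of 0.18, within the range but above it with a pseudocount of 5, and 0 of 10 were 2-fold apart.

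Cardiac mesoderm and epicardial transcription factors had the highest median, 1.25. Of 10 members at or above 1 RPKM, 4 were higher in heart, none in bone marrow and 6 neither, and 8 members were below 1 RPKM in both libraries. Gata6, a zinc finger factor of heart development, stood at 14.0 RPKM in heart and 3.48 in bone marrow, and Tbx2, Mef2c and Meis1 had log2 ratios of 2.13, 1.68 and 1.37. The cardiac factor gene Nkx2-5 was listed at 0 in both libraries. Hand2 and Gata4 went toward heart, at 2.85 and 1.20 RPKM against 0.00788 and 0.00949, under the floor of 5. The epicardial factor genes did not stand apart: Tbx18 stood at 12.8 RPKM in heart and 10.6 in bone marrow. Wt1 and Tcf21 were below 1 RPKM in both libraries.

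Cholesterol synthesis genes were higher in bone marrow, 11 of 20, with none higher in heart, 9 neither and a median of -1.09. Cyp51, which encodes lanosterol demethylase, stood at 117 RPKM in bone marrow and 29.9 in heart, and the farnesyl diphosphate synthase gene Fdps at 141 and 47.3. Wnt pathway genes had a median of -0.99, with 4 of 15 higher in bone marrow, 1 in heart and 10 neither. Rspo2 and Rspo3, which encode secreted amplifiers of Wnt signalling, went opposite ways, with log2 ratios of -4.97 and 4.69, and the R-spondin receptor gene Lgr5 had -4.58. Notch pathway genes had a median of -0.57, just below the random range, with 2 of 7 higher in bone marrow, 1 in heart and 4 neither; this call was lost under each alternative except a pseudocount of 5. The Notch modifier gene Lfng had a log2 ratio of -2.65 and the ligand gene Jag1 -1.21. Immediate early and stress genes had a median of -0.48, with 4 of 18 higher in bone marrow, none in heart and 14 neither, and were no longer apart with members below 5 RPKM left out. Fosl1, an AP-1 component gene, had -2.31 and the stress response gene Chac1 -2.18.

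Mesenchymal surface and lineage markers had a median of 0.18 at the upper edge of the random range, and lay above it under most alternatives, each scaling run on the lists included, with 7 of 18 higher in heart, 3 in bone marrow and 8 neither. Eng and Thy1, which encode the stromal antigens endoglin and Thy-1, stood at 33.9 and 16.7 RPKM in heart and at 0.576 and 0.0603 in bone marrow. Haematopoietic niche factors had a median of 0.05, with 4 of 13 higher in heart, 4 in bone marrow and 5 neither. Grem1, which encodes a BMP antagonist, stood at 168 RPKM in heart and 17.3 in bone marrow. TGF-beta and BMP response genes had a median of 0.01, with 3 of 19 higher in heart, 4 in bone marrow and 12 neither; the inhibitory Smad gene Smad6 had a log2 ratio of -2.70. Of neural stem cell and neural crest markers, 15 of 20 were below 1 RPKM in both libraries, and the rest had a median of 0.00, with Nes higher in heart and Snai2 and Tubb3 higher in bone marrow (-2.12 and -2.51).

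Hox genes, which encode positional transcription factors, had a median of 0.10, within the random range, because they went opposite ways, and below it with members below 5 RPKM left out. Of 24 at or above 1 RPKM, 6 were higher in heart, 8 in bone marrow and 10 neither. Grouped by cluster after the values were seen, 8 of 9 HoxC genes were at or above 1 RPKM in bone marrow and 0 in heart, and 8 of 10 HoxB genes in heart and 0 in bone marrow. Hoxc10 had 2422 reads in bone marrow and 0 in heart, and Hoxb2 stood at 13.4 RPKM in heart and 0.546 in bone marrow. HoxA genes went both ways, with 3 at least 2-fold higher in heart and 3 in bone marrow at a floor of 1 RPKM. Hoxa10 stood at 15.7 RPKM in bone marrow and 0.00943 in heart, and Hoxa5, chosen after its values were seen, at 3.73 and 14.2. No HoxD gene reached 1 RPKM in either library.

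**Figure D3:**
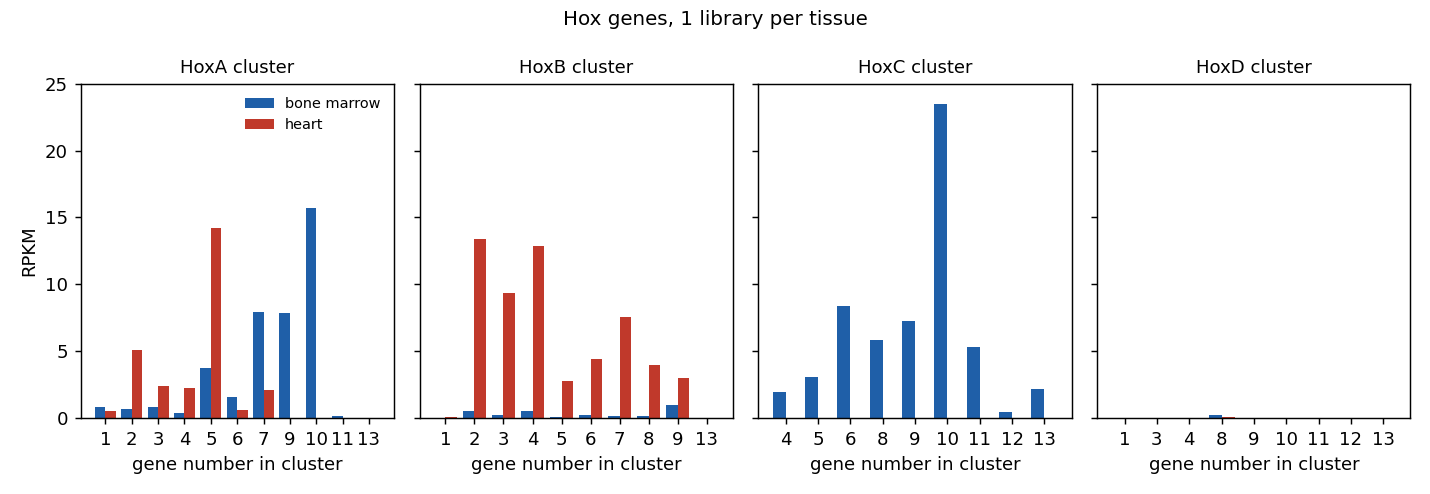
Bars give the RPKM of each Hox gene in the bone marrow library (blue) and the heart library (red), ordered by gene number within the HoxA, HoxB, HoxC and HoxD clusters. HoxC genes appear in bone marrow up to 23.5 RPKM, and HoxB genes in heart up to 13.4 RPKM.

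Most markers of other cell types were below 1 RPKM in both libraries. Of 18 cardiomyocyte genes, 17 were below 1 RPKM in both, as were 15 of 18 macrophage and monocyte markers, 12 of 15 endothelial markers and all 17 neutrophil, erythroid and lymphoid markers found. The leukocyte gene Ptprc stood at 0.00469 RPKM in bone marrow and was listed at 0 in heart. The endothelial marker Erg, an ETS transcription factor gene, met the 2-fold rule at 6.06 RPKM in heart and 0.299 in bone marrow, while Cdh5, which encodes the endothelial cadherin, was at 0.00734 in heart. The other endothelial and macrophage markers at or above 1 RPKM were chosen after their values were seen. In bone marrow and heart, Flt1 stood at 2.35 and 2.23 RPKM, Vwf at 1.13 and 0.00768, Cd53 at 1.03 and 4.80, Cd14 at 2.79 and 2.97 and Lyz2 at 1.05 and 1.08. Of the 5 sex-linked genes, Xist was at 0.0155 RPKM in bone marrow and 0.00946 in heart, and the Y-linked Ddx3y at 28.1 and 26.4 and Uty at 3.94 and 4.22. The Y-linked Eif2s3y and Kdm5d were 8.86-fold and 9.47-fold higher in heart, at 14.2 and 2.67 RPKM there and 1.61 and 0.282 in bone marrow. Kdm5d was thus under the floor of 5 RPKM.

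The ribosomal, mitochondrial, histone, glycolysis and hypoxia, and reference gene lists lay within the random range on the main settings. Of 29 ribosomal protein genes and 13 mitochondrially encoded genes, 0 were 2-fold apart, with medians of -0.15 and -0.35. Of 6 replication-dependent histone genes at or above 1 RPKM, 0 were 2-fold apart, with a median of -0.62, and reads shared between histone copies make these values uncertain. The random range for these 6 was wide, from -0.83 to 0.74. Glycolysis and hypoxia genes had a median of -0.23 (below the range with members below 5 RPKM left out), with 2 of 17 higher in bone marrow, Ndrg1 and Eno1 (-2.17 and -1.17), and 15 neither. Of 18 commonly used reference genes, 3 were higher in bone marrow and 15 neither, with a median of -0.41. Those 3 were the transferrin receptor gene Tfrc (-2.35), Hprt (-1.26) and Actb (-1.08), and Actb was under 2-fold with median ratio, upper-quartile and same-sum scaling. The list lay below the random range with a pseudocount of 5 and with random lists not matched.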

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

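The counts of 2-fold genes kept within 1.5 times under the 5 scalings, a pseudocount of 0.1, summed rows and leaving out chromosome 10. They were 383 (heart) and 424 (bone marrow) with a pseudocount of 5, 263 and 315 with a floor of 20 RPKM, and 257 and 229 at 4-fold. With a floor of 1 RPKM or none, 883 were higher in heart and 1052 in bone marrow. A pseudocount of 1 makes these settings equal. Each of these follows from the rule admitting more or fewer genes. The log2 ratio of Postn was -0.017 with median ratio scaling, -0.079 with upper-quartile scaling, -0.094 with the trimmed mean and -0.073 with the same RPKM sum. For Nes it was 2.77 with a pseudocount of 0.1 and 1.15 with 5. Pearson's r was 0.928 with a pseudocount of 5 and 0.838 over genes at or above 1 RPKM, where rho was 0.830. The median of secreted factors acting on macrophages moved to 0.031 with all measured members kept. The 13 members then added were below 1 RPKM in both libraries, where a pseudocount of 1 holds log2 ratios near 0. Theirs ran from -0.029 to 0.42, so the move reflects genes at low levels. Of 134 named genes, 106 had a log2 ratio of at least 1 in size, counted without the floor of 5 RPKM, which Kdm5d does not reach. Of these 106, 0 changed sign and 7 were under 2-fold in some alternative. The 7 were Actb under 3 scalings, Fos under median ratio scaling, and Jag1, Kdm5d, Mef2c, Meis1 and Notch3 with a pseudocount of 5. Of the named genes with smaller log2 ratios, 3 changed sign under some scaling. Scaling moves the log2 ratio of genes abundant in heart by up to 0.15 and of genes low there by less. The lists called apart numbered 15 to 19; with members below 5 RPKM left out, interferon-stimulated genes, growth factors, immediate early genes and Notch genes were no longer apart, and Hox, adipocyte, glycolysis and hypoxia, and mesenchymal lists were. The mesenchymal list was also apart with a pseudocount of 5, the 4 scalings run on lists, summed rows and all measured members kept. With all members kept, the chondrocyte list was no longer apart and the cardiomyocyte list, with 1 member at or above 1 RPKM, was. Reference genes were apart with a pseudocount of 5 and with random lists not matched, and antigen presentation genes with a pseudocount of 5. Depth limits genes with few reads, and differences between cultures of 1 tissue are not covered.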

Other observations

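Mgp, which encodes the calcification inhibitor matrix Gla protein, stood at 4907 RPKM in heart against 189 in bone marrow, and in heart the value of Spp1 alone was higher. Genes outside the rule were chosen after their values were seen. The imprinted noncoding RNA gene H19 stood at 38.2 RPKM in heart and 0.250 in bone marrow, the basement membrane collagen gene Col15a1 at 374 and 13.7, and Thbd, which encodes thrombomodulin, at 43.9 and 0.338. In bone marrow, the tendon transcription factor gene Scx stood at 23.7 RPKM against 0.529 in heart, the collagen-binding integrin gene Itga11 at 156 against 6.43, and Tnfrsf11b, which encodes the osteoclast inhibitor osteoprotegerin, at 62.9 against 4.78. Thbs1, which encodes thrombospondin 1, stood at 1269 RPKM in bone marrow and 117 in heart.

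The tests of GC content, gene length and copy number on chromosome 10 were set before their results were seen, and the test of its neighbourhoods and all tests on Cdkn2a and on the chemokine genes after. For the neighbourhoods and for loss of Cdkn2a, another form of the test was tried after the first had been seen; both other forms went against the explanation, and their values are given below. The bootstrap interval of the interferon-stimulated genes was also added after their median was seen. Before that, the median alone had gone against a general interferon response.

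Chromosome 10 genes were lower in heart than other genes, and the chromosome was singled out for that shift. The bootstrap intervals in this paragraph treat genes as independent, although neighbouring genes may move together. They do not cover differences between cultures. The median log2 ratio of its 322 genes at or above 5 RPKM in both libraries lay -0.43 from that of all genes (bootstrap over genes -0.50 to -0.37), against -0.26 for chromosome 12 (its 5 segments -0.28 to -0.25) and -0.07 to 0.15 for the others, although segments within chromosome 4 ran from -0.35 to 0.41. The shift stayed at -0.42 after removing the medians of 20 GC bins and at -0.41 after 20 length bins, which argues against either trend as the whole cause. A few regulated neighbourhoods as the whole cause are argued against by 7 of 8 segments shifted by more than 0.2, from -0.56 to -0.35. That is more segments than the explanation allowed. The other segment stood at -0.15, so the result set against it, a shift of all segments, was not reached. The shift without the 2 most shifted segments was -0.40 (bootstrap -0.46 to -0.29). This form decides nothing more, because the other segments had been seen to be shifted. An unequal copy number stays open, since the 76.4% of genes below the all-gene median, although past the bound of 75% set for it, restates the shift (chromosome 12 had 72.7%), and tissue and medium were not tested.

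Cdkn2a and Cdkn2b were near absent in bone marrow, with 30 reads of Cdkn2a against 4475 in heart. A low level of every gene in the neighbourhood is argued against by 4 flanking genes within 500 kb with RPKM over 2-fold higher in bone marrow, Dmrta1 with 1328 reads against 2 and 3 predicted genes; with a pseudocount of 1, 3 of the 4 were 2-fold apart. Mtap went the other way, with 934 reads against 2237, and a predicted gene between it and Cdkn2a had 264 reads against 0, while the wider segment of chromosome 4 that holds them was shifted by 0.41 toward heart and the next 3 by 0.34, 0.27 and 0.33. Loss of the whole Cdkn2a gene from every bone marrow cell cannot be told apart from low expression: its bone marrow reads per heart read were 5.46 times the median of the 20 lowest such ratios (counting interval 3.68 to 7.80, with the bound of 5 inside), and the other form, 16.9 times a leakage limit, rests on Mmp3 alone. A smaller deletion, silencing and the medium may each account for it and were not tested.

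Some chemokine and acute phase genes were high in heart, as with Saa3 and Ccl8, which were taken from the top of the ranking, and no list of such genes was set in advance. Macrophages carried in the heart culture are argued against by the median of their markers there, 0.0153 RPKM, with Ptprc, Tyrobp and C1qa listed at 0. A general interferon response of 2-fold or more is argued against for the listed genes in these 2 libraries. Their median log2 ratio was 0.28, and the bootstrap interval of -0.12 to 0.86 lay below the 1 set for such a response. A weaker response stays open, since the median lay above the random range, with 13 of 19 members above 0 and 6 below. The tissue of origin and the medium, which differ together, may each account for the pattern and were not tested.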
